A study of Mus musculus with 6 samples.

How the data were processed

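Total RNA of 6 samples labelled with Cy3 was hybridised to one-colour Agilent arrays of mouse circular RNAs, 3 from CIH mice and 3 from control mice. Samples were grouped by their titles. No label says that the arrays of a group came from separate mice beyond calling them replicates, so p-values measure only the spread between these samples, which may be technical. The labels conflict on tissue, strain and extraction, and no label describes a step that removes linear RNA.

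The authors deposited 1 scanner file per array and 1 table of processed values. Per the file headers, the deposited intensity values were extracted with Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name version 9.1. The intensity used was the processed signal, which per the file headers was background-subtracted and detrended within each array and not normalized between arrays. The deposited table holds log2 values for 14218 of the 14236 circular RNA probes. How the authors made these log2 values is not given in the sources used here. Their columns have medians of 6.79, 6.81 and 6.79 for CIH 1, 2 and 3 and 6.79, 6.78 and 6.78 for control 1, 2 and 3. They ranked probes like the scanner values of the same array (Spearman's rho from 0.992 to 0.999), and correlated at r = 0.999 with normexp-corrected, quantile-normalized signals. Their scale and direction were settled by this comparison, and their offset stays unknown. Columns of per-sample values left unused numbered 0.

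Spots marked as outliers were left out and saturated spots would have been kept. Log2 intensity was scaled by subtracting each array's 75th percentile over 14330 non-control probes, and spots of a probe were averaged. A probe counted as well above background on an array when more of its unmarked spots were so than not, a rule set after the values had been seen. Probes were tested when well above background on all 3 arrays of at least 1 group and measured on at least 2 arrays per group. This left 13374 probes, 13329 for circular RNAs and 45 for mRNAs, with 907 circular RNA probes not tested. The other 44 non-control probes (15 custom, 14 circular RNA control and 15 negative probes) were kept outside the test, a choice made after seeing the values. Differences are CIH minus control, fitted with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all 13374 probes and a threshold of 0.05. A looser list took an unadjusted p under 0.05 and at least 1.5-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

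The rule for named probes, fixed before the data were examined, took probes past the adjusted threshold with groups that do not overlap. Remaining places went to the smallest unadjusted p in each direction, again only with groups that do not overlap. They were limited to 2 probes a direction where no table names the probes. Of 50 mRNA probes, 44 were named by matching their accession to the RefSeq gene table of GRCm38.p6, and 6 kept no gene name. The array's own genome build is not given in the sources used here, so no coordinates are printed. The mRNA genes described are those at an unadjusted p under 0.05, the members of the 19 lists, and *Apoe*, *Pex11a*, *Anxa8* and *Gpi1*, all chosen after seeing the values. *Rab5a* is named only for the fit with replicate number as a block.

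Planned tests of gene lists by host gene, of circular RNA classes, and of circular RNAs sharing a host gene were not run, since they need a host gene or class per probe, which was not used here. Lists with fewer than 5 tested members were not tested.

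Arrays of the same replicate number were checked for shared deviations from their group means across probes. The correlations were 0.181 for number 1, 0.108 for number 2 and 0.806 for number 3, each above the bound of 0.1 set for treating the numbers as pairs. The second passed narrowly. CIH 1 correlated more highly with control 2 (0.457) and CIH 2 with control 1 (0.700) than with the control of their own number. The pairing comes from these values and the titles' numbers, and the labels do not say what a number shares. No pair of arrays held identical values.

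The fit was tested on simulated data for 13257 probes, drawn independently of each other with each probe's real spread, and 200 were changed. The adjusted test recovered 0% of probes changed by 2-fold, 33% by 4-fold and 81.5% by 8-fold. The looser list recovered 60%, 92% and 99%, with 633 to 720 unchanged probes among its calls. At a lower spread (SD 0.247) the adjusted test recovered 91.5%, 100% and 100%. Real probes varied together across arrays, and other splits of the 6 arrays into groups of 3 gave looser lists of 0 to 3104 probes. The simulated recoveries and false calls therefore need not hold for the real arrays.

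The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, a percentile over probes well above background on all arrays, another filter on dim probes, and the authors' table. Replicate number or slide as a block, slide 1 alone, eBayes with trend and robust options, array weights and leaving out each array were also tried. The files lack the mean signal that the planned normexp needed, so the median signal was used. That setting and slide 1 alone were added after seeing the data. Many of these fits, and the 10 splits of the arrays, had been explored before their final form was written.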

Results

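Circular RNAs, closed RNA loops formed by back-splicing of a transcript, were measured in mice kept under chronic intermittent hypoxia (CIH) and in control mice. Oxygen in the CIH chamber was lowered to 6% with nitrogen and then brought back to 21%, each phase taking 60 seconds. The mice went through 30 such cycles an hour for 8 hours daily over 8 weeks. The series title places the question in liver injury from obstructive sleep apnoea, which such cycles of low oxygen model. Each group held 3 one-colour arrays, named here by group and replicate number. The labels gave 3 tissue names: liver in the study design, kidney in the source name and pancreas in the sample characteristics. They also gave a blood RNA kit for the extraction, and both an APOE and a BALB/c strain name. The tissue is therefore not named below.

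Each array carried 14236 circular RNA probes with 1 spot each and 50 mRNA probes with 10 spots each. The share of circular RNA probes well above background was 94.7%, 96.6% and 97.0% on CIH 1, 2 and 3. It was 95.4%, 73.9% and 96.0% on control 1, 2 and 3. Signal at the 75th percentile was 136, 275 and 205 intensity units on the CIH arrays and 147, 123 and 144 on the control arrays. The group difference in log2 signal at that percentile was 0.52 (exact permutation p = 0.3, 2-sided, adjusted p = 0.5 over 5 array measures). No spot was saturated. With 3 arrays a group, the smallest p an exact permutation test could give was 0.1, and the number of arrays limited the precision of every difference.

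Circular RNA profiles grouped the arrays only partly by treatment. CIH 1 was most like control 1, with Pearson's r = 0.986 across probes, the highest of all pairs of arrays. Its correlation with CIH 2 was 0.929 and with CIH 3 was 0.893. The lowest correlation, 0.728, was between CIH 2 and control 3. CIH 3 correlated with control 3 at 0.937, above its 0.846 with CIH 2. Probes are not independent replicates, so these values describe the arrays only.

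**Figure D1:**
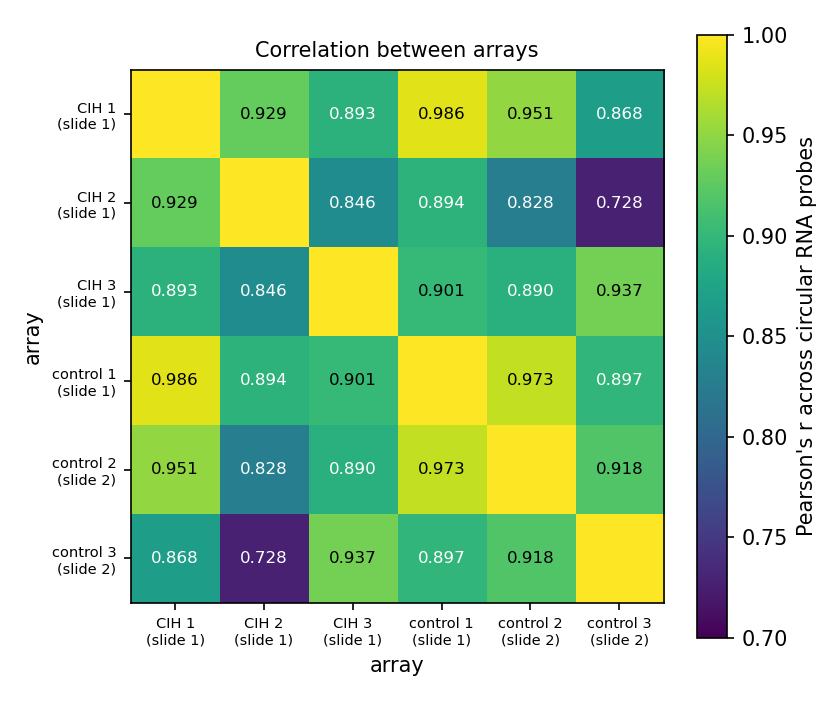
Pearson's r between each pair of the 6 arrays across 13212 circular RNA probes, with the array and its slide on both axes and colour for r. CIH 1 and control 1 reached 0.986, and CIH 2 and control 3 had the lowest value, 0.728.

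No circular RNA passed the test between CIH and control mice. Among 13329 tested probes, 1824 (13.7%) lay at an unadjusted limma p under 0.05, all of them at least 1.5-fold apart, where 666 were expected by chance. Of this looser list, 1522 were higher in CIH (83.4%), with a median of 2.39-fold, and 302 were lower, with a median of 2.19-fold. The smallest adjusted p was 0.315 (limma, Benjamini-Hochberg), so the looser list is not a list of changed circular RNAs. Probes varied together across arrays, so its count can also lie far from 666 by chance. Other splits of the arrays gave 0 to 3104 probes. Directions follow the sample titles. The deposited scanner files carry the letter C for arrays titled CIH and T for arrays titled control. If C stood for control, every sign given here would turn.

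The probes below are given by ID, since the files do not pair them with circular RNA names or host genes, and log2 levels are relative to the array's 75th percentile. The higher probe with the smallest p, ASCRP4005756, had a log2 level of 1.25 ± 0.60 (SD, n = 3) in CIH and -0.92 ± 0.57 in control. This was a 4.51-fold difference, 2.17 on the log2 scale (SE 0.44, limma, adjusted p = 0.315). ASCRP4006166 differed by 1.9 (SE 0.39), but was well above background on only 1 control array, and its difference was 0.51 after normexp background correction and 0.41 in the authors' deposited values. ASCRP4008575 had a log2 level of 1.74 ± 0.67 (SD, n = 3) in CIH and 3.37 ± 0.14 in control, 3.10-fold lower in CIH. ASCRP4003132 was also 3.10-fold lower, a log2 difference of -1.63 (SE 0.42) that was -0.66 after normexp and -0.84 in the authors' deposited values. All 4 had the same adjusted p of 0.315 (limma). For each the 3 arrays of one group lay above the 3 of the other, which the rule for naming them required.

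**Figure D2:**
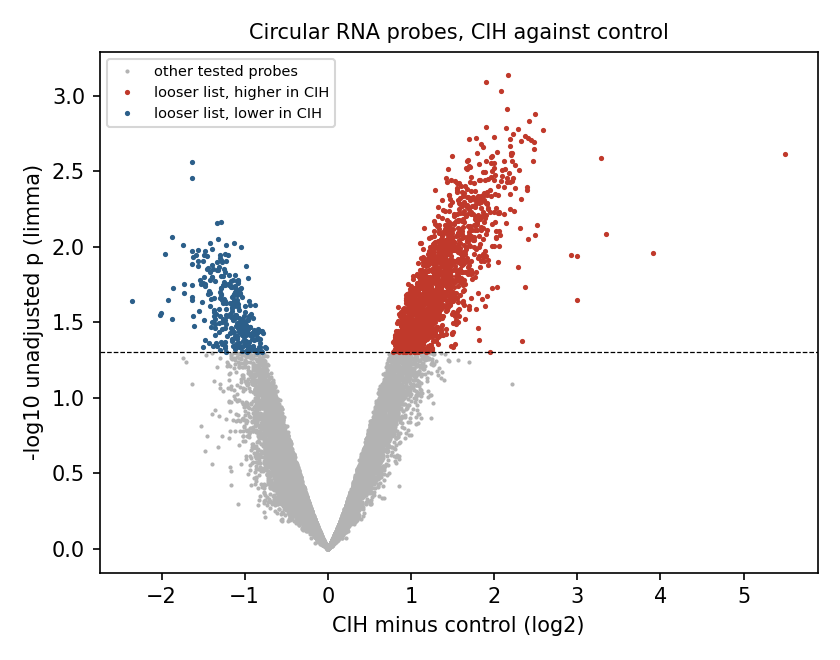
Difference of each tested circular RNA probe (CIH minus control, log2, horizontal axis) against minus log10 of its unadjusted limma p (vertical axis), with 1 point per probe and a dashed line at 0.05. Of the points above the line, 1522 lay on the right (higher in CIH) and 302 on the left, and none passed after adjustment.

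The groups did not overlap for 2731 tested probes (20.5%), where chance gives 10%. In the looser list this held for 1476 probes (80.9%). That list was chosen by p and fold from the same values, so its share adds no support and cannot be set against chance. The typical spread between arrays was wide, with a median SD of 0.52 in CIH and 0.44 in control on the log2 scale. The median probe differed by -0.06, whereas the median of an array's probes was 0.14 higher in CIH (exact permutation p = 0.1, adjusted p = 0.5), so the sign of the overall shift depended on how it was taken. Scaling to the array median instead lowered every difference by 0.14 and gave 1099 higher and 564 lower probes (66.1% higher). After normexp background correction the looser list held 534 higher and 329 lower (61.9%). Probes well above background in only 1 group could enter the test. Over those well above background on all arrays, the looser list held 1041 higher and 329 lower (76.0%).

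The 3 CIH arrays and control 1 shared slide 1, and control 2 and 3 were on slide 2. With slide as a block, which gives the difference within slide 1, the looser list fell to 30 higher and 23 lower probes and none passed the adjusted test. With replicate number as a block it held 2309 higher and 904 lower, again with none past the adjusted threshold (smallest adjusted p = 0.0852, limma). It held 606 probes without CIH 2, 690 without control 2 and 2747 without CIH 3. The adjusted test passed 1 probe without CIH 1. With slide 1 alone the looser list held 79 higher and 101 lower probes, in a fit with a single control array and the same variance for every probe. Within slide 1, ASCRP4005756 differed by 1.55 (SE 0.64), ASCRP4006166 by 1.68 (SE 0.63), ASCRP4008575 by -1.49 (SE 0.65) and ASCRP4003132 by -1.60 (SE 0.67).

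Of the mRNA probes, which target linear transcripts of named genes, 45 were tested. Of these, 9 had an unadjusted limma p under 0.05, where 2.25 were expected by chance. Since probes varied together across arrays, such a count can lie far from that number by chance. All 9 were higher in CIH, by 2.14-fold to 5.0-fold, among 20 positive and 25 negative differences. They were *Acaa2*, *Cpt1a*, *Gsta4*, *Actb*, *Nup50*, *Lhfp*, *Uhrf1bp1l*, *H2-Q7* and *Kcnn2*. Without a block, none passed the adjusted threshold, either over all tested probes (smallest adjusted p = 0.315, limma) or adjusted over the list alone. *Lhfp*, *Acaa2*, *Nup50*, *Actb*, *Gsta4* and *Cpt1a* shared the smallest adjusted p over the list alone, 0.0950 (limma). With replicate number as a block, 7 of the 9 passed adjusted over the list alone: *Lhfp*, *Acaa2*, *Gsta4*, *Cpt1a*, *Actb*, *Nup50* and *Kcnn2*. The smallest adjusted p was then 0.0238 (limma), in a range of 0.00763 to 0.793 over all alternatives, and 0 passed over all tested probes. All 9 were higher in CIH in each of the 3 numbered pairs. In 8 of the 9 the 3 CIH arrays lay above the 3 control arrays, where any pairing gives that result. The numbered pairs therefore add little support. Counting either direction, the groups did not overlap in 9 of the 45 (20%), where chance gives 10%, and in the ninth gene, *Anxa8*, CIH lay below control. This comparison and the choice of these genes were made after the values had been seen.

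*Acaa2* and *Cpt1a*, both enzymes of mitochondrial fatty acid oxidation, had the largest differences, though with array weights *Nup50* exceeded both, at 1.34. *Acaa2*, the thiolase of the last step of the cycle, had a log2 level of 2.58 ± 1.63 (SD, n = 3) in CIH and 0.26 ± 0.22 in control. Its difference of 2.32 (SE 0.69) was a 5.0-fold one. *Cpt1a*, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, had 0.86 ± 1.36 in CIH and -1.04 ± 0.40 in control. Its difference was 1.9 (SE 0.62), or 3.73-fold. Both genes were uneven across the CIH arrays. Without CIH 2 the differences were 1.60 for *Acaa2* and 1.28 for *Cpt1a*, without CIH 1 they were 3.21 and 2.63, and with array weights 1.15 and 1.11. The unadjusted limma p was no longer under 0.05 for *Cpt1a* without CIH 2 and for *Acaa2* with array weights. *Acaa2* lay at 0.81, 4.03 and 2.90 on CIH 1, 2 and 3, and *Cpt1a* at -0.59, 2.10 and 1.08. For all 9 genes CIH 2 was the highest CIH array and CIH 1 the lowest, the array most like control 1. Signal at the 75th percentile before scaling had the same order, at 136, 275 and 205 on CIH 1, 2 and 3.

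*Gsta4*, a glutathione transferase that detoxifies products of lipid peroxidation, was 2.66-fold higher in CIH. Its log2 level was 0.23 ± 0.87 (SD, n = 3) in CIH and -1.18 ± 0.11 in control, a difference of 1.41 (SE 0.45). That difference was 0.93 without CIH 2, 1.77 without CIH 1 and 0.87 with array weights. *Actb*, the cytoskeletal beta-actin often used as a reference gene, differed by 1.45 (SE 0.46), and was higher in CIH under each of the scalings tried. *Nup50*, a nuclear pore protein, differed by 1.58 (SE 0.50) and was well above background on 2 of the 3 control arrays. *Lhfp* differed by 1.51 (SE 0.44). *H2-Q7*, a non-classical class I histocompatibility gene, differed by 1.17 (SE 0.47) and *Uhrf1bp1l* by 1.1 (SE 0.41). Without CIH 2 they differed by 0.76 and 0.75, no longer with an unadjusted p under 0.05, and without CIH 1 by 1.44 and 1.33. *Kcnn2*, a calcium-activated potassium channel, differed by 1.67 (SE 0.68), with CIH 1 at -4.36 below control 3 at -3.65, and was well above background on 2 of the 3 control arrays. Its difference was 1.09 without CIH 2, no longer with an unadjusted p under 0.05, and 2.48 without CIH 1. After normexp background correction *Nup50* differed by 0.70, *Kcnn2* by 0.61 and *Lhfp* by 0.94, and *Nup50* and *Kcnn2* no longer had an unadjusted p under 0.05.

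**Figure D3:**
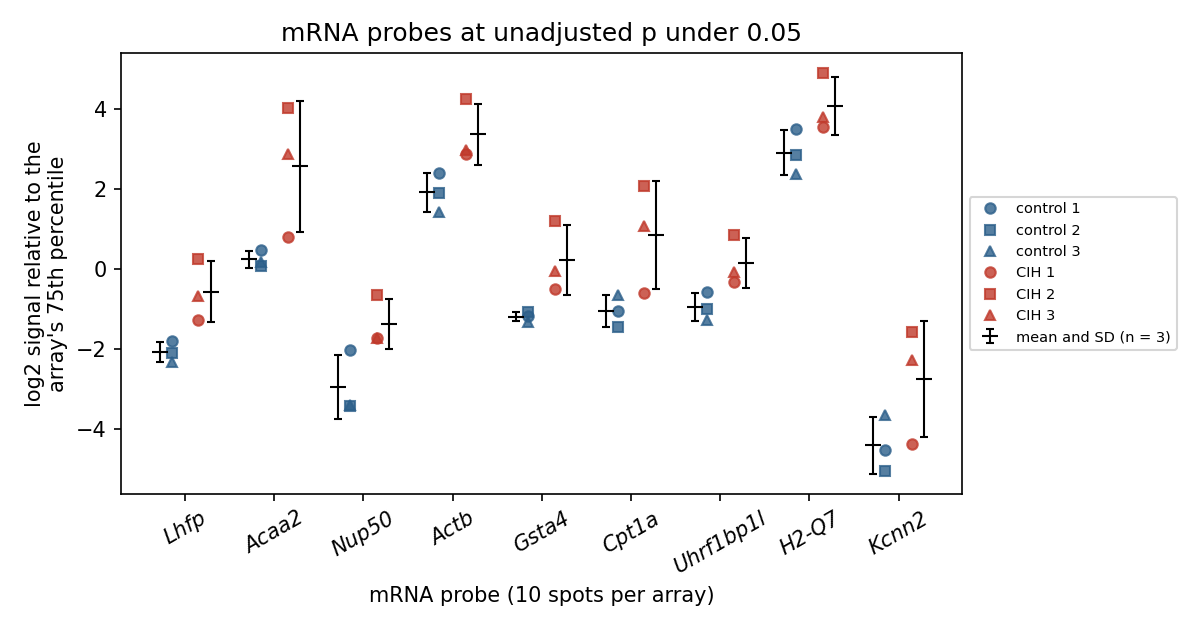
Log2 signal relative to the array's 75th percentile (vertical axis) of the 9 mRNA probes at an unadjusted limma p under 0.05 (horizontal axis), 1 symbol per array, with the mean and SD of each group of 3 beside them. For *Acaa2* the CIH arrays lay at 0.81, 4.03 and 2.90 and the control arrays at 0.50, 0.08 and 0.20.

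Lists of genes written before the data were examined had few members among these probes. Of 19 lists, 14 had none and the other 5 had at most 2, so no list was tested. The lipid and cholesterol list held *Cpt1a* and *Ppara*, the nuclear receptor that drives fatty acid oxidation genes. *Ppara* differed by -0.16 (SE 0.44). The autophagy list held *Atg3*, at 0.51 (SE 0.58), and the cell cycle list *E2f1*, at -0.38 (SE 0.37). The pancreas list held *Chgb*, a protein of endocrine secretory granules, at -0.80 (SE 0.43), and the neural list *Mbp*, a myelin protein, at -0.59 (SE 0.43). None of these 6 genes passed the adjusted test. Leaving out 1 array moved *Atg3* to between 0.00076 (without CIH 3) and 1.04 (without CIH 1), *E2f1* to between -0.64 (without CIH 1) and -0.22 (without CIH 2), *Chgb* to between -1.13 (without control 3) and -0.57 (without control 2), and *Mbp* to between -0.83 (without control 2) and -0.23 (without CIH 2). *Mbp* was well above background on 2 of the 3 control arrays.

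*Apoe*, the apolipoprotein whose name the sample titles carry, lay at 1.39, 2.6 and 2.0 on CIH 1, 2 and 3 and at 1.44, 1.47 and 1.47 on control 1, 2 and 3. Its difference of 0.53 (SE 0.39, limma, adjusted p = 0.567 over the list alone) did not pass, and was 0.23 without CIH 2, 0.84 without CIH 1 and 0.12 with array weights. The labels do not state a knockout, and where the probe lies in the gene is not given, so its level checks no label. *Gpi1*, the glycolytic phosphoglucose isomerase, differed by 0.75 (SE 0.56), a value of 1.45 without CIH 1, 0.41 without CIH 2 and 0.39 without CIH 3. *Anxa8*, an annexin, differed by -0.83 (SE 0.38), and by -0.54 without CIH 2.

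The median SD between the 10 spots of a probe on 1 array was 0.07, against 0.66 between CIH arrays and 0.41 between control arrays. With replicate number as a block, 12 genes had an unadjusted p under 0.05, with *Rab5a* higher and *Anxa8* and *Chgb* lower in addition to the 9. With slide as a block all 9 differences stayed positive, a sign that non-overlapping groups fix for 8 of them. None then had an unadjusted p under 0.05. Within slide 1, *Acaa2* differed by 2.08 (SE 0.98), *Cpt1a* by 1.89 (SE 0.89), *Gsta4* by 1.40 (SE 0.70) and *Actb* by 0.96 (SE 0.68). The other 5 genes differed there by 0.58 (*H2-Q7*) to 1.77 (*Kcnn2*). Without CIH 1, 4 genes (*Acaa2*, *Cpt1a*, *Kcnn2* and *Lhfp*) passed adjusted over the list alone. Without CIH 2, 5 genes had an unadjusted p under 0.05.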

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

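The comparison of dim with bright probes was fixed before its result was seen. The tests of scaling, slide, exchanged labels and sample splits were chosen after, and the bounds for scaling were set with most of its values known.

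A custom probe with an unstated target, CUST_9_PI419532418, lay outside the comparisons and was higher on all 3 CIH arrays than on all 3 control arrays. Its log2 levels were 1.76, 3.03 and 2.53 on CIH 1, 2 and 3 and 1.49, 1.1 and 1.14 on control 1, 2 and 3. The difference of 1.20 (SE 0.40, limma) had an adjusted p of 0.326 over the 44 such probes. Of these 44, 2 were higher on all CIH arrays and 7 lower, and chance puts 5% in each direction. Of the 7, 6 were circular RNA control probes, with 12 of 14 such probes below 0 (median difference -0.45). Of the negative probes, 14 of 15 were below 0 (median -0.51). Before scaling, the negative probes' mean differed by 0.01 between the groups (exact permutation p = 1), and the percentile subtracted in scaling was 0.52 higher in CIH.

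More circular RNA probes of the looser list (unadjusted p under 0.05 and at least 1.5-fold) were higher than lower in CIH (83.4% of 1824). The share was 61.9% with normexp, 66.1% with median scaling, 76.6% with quantile normalization and 87.2% with the percentile over probes above background on all arrays. Its lowest value lay between the bounds of 60 and 70% set for and against scaling as the source. Over the higher probes the CIH arrays exceeded control 1 of their slide by a median of 0.74 and controls 2 and 3 by 1.54, but these probes were chosen for exceeding the controls, so the gap decides nothing. Over the lower probes control 1 lay at -0.04 from the control mean, between control 2 (0.29) and control 3 (-0.24). Scaling, slide and CIH cannot be told apart here, since slide 1 held a single control array and the lowest share passed neither bound.

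Of 10 splits of the 6 arrays, 2 gave a looser list as large, counting the real one (real 1824, highest other 3104). These are too few splits for a share under 0.05. The adjusted count was 0 in the real split and at most 0 in the others, so 10 of 10 reached it by construction, which says nothing about chance. The larger looser list came from setting CIH 1, CIH 2 and control 1 against the rest, a structure of the samples that crosses the treatment. The smallest adjusted p of that split was 0.183 (limma). With CIH 1, control 1 and control 2 against the rest it was 0.188, and both lay below the real 0.315. Among the 4 splits that part all 3 numbered pairs, 1 gave a list as large (the real one, highest other 350), again too few for a share under 0.05. The other 6 splits part only 1 pair each.

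CIH 1 was more like control 1 (r = 0.986) than like CIH 2 (0.929) or CIH 3 (0.893). A shared slide would also draw CIH 1 to CIH 2 and CIH 3, yet its correlation with control 2 on the other slide was higher, at 0.951. An exchange of labels between CIH 1 and control 3 would put control 3 near CIH 2 and CIH 3. Its correlation with CIH 2 was 0.728, but with CIH 3 it was 0.937, above its 0.918 with control 2. These values point both ways, so they do not decide on such an exchange. A weak response of the CIH 1 mouse, a single wrong label and an exchange with a sample outside the series were not tested and stay open.

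CIH 3 and control 3 deviated from their group means in the same way (r = 0.806 across probes). Signal on probes without a target would act most on dim probes, yet the correlation in the fifth of probes with the lowest signal was 0.691, against 0.840 in the fifth with the highest, a difference of -0.149. Noise also lowers a correlation among dim probes, so the test cannot decide on such signal. The negative probes, which have no target, were brightest on these arrays before scaling, at 4.04 on control 3 and 3.88 on CIH 3. They lay at 2.55 to 3.00 on the other 4, so such signal stays open as a source. The arrays lay on 2 slides, which excludes a shared slide, while a shared day, cage or RNA preparation is not given in the labels and stays open.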

How the results depend on the processing

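Normexp, slide 1 alone and all alternatives for the mRNA results were chosen after seeing the data. The adjusted count of circular RNA probes was 0 except with slide 1 alone (2) and without CIH 1 (1), a range of 0 to 1 over the left-out arrays. The looser list (1824) held 863 with normexp, 974 in the authors' value table, 3213 with the replicate block, 53 with slide as a block, 180 with slide 1 alone, and 606 to 2747 without 1 array. Its share of higher probes was 43.9% with slide 1 alone, 56.6% with slide as a block, 71.9% with the replicate block, 76.6% after quantile normalization and 81.1% with array weights. Without 1 array the share lay between 66.5% (without CIH 1) and 93.3% (without control 2). The overall shift (-0.06) was 0.030 with normexp, -0.12 with quantile normalization, -0.19 with median scaling and 0.00092 with the percentile over probes above background on all arrays. It was -0.16 over only such probes, 0.026 with slide as a block and with slide 1 alone, 0.044 with array weights, and -0.13 to 0.067 without 1 array. The mRNA genes at an unadjusted p under 0.05 (9) numbered 0 with slide as a block, 3 with slide 1 alone, and 5 to 13 without 1 array. Those passing adjusted over the list alone (0) numbered 7 with the replicate block, and 0 to 4 without 1 array. The replicate block took the genes at an unadjusted p under 0.05 to 12 (10 higher, 2 lower) and passed no circular RNA. The cause of these moves was not tested, except that slide 1 alone holds fewer arrays and gave every probe 1 common variance, so its calls show nothing about single probes.

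Of 374 recomputed differences of the 22 named probes and genes, 371 kept their direction. Much of that count was fixed in advance. The replicate block, the other filters on dim probes and the eBayes options left each difference as it was. Where the groups did not overlap, leaving out an array, array weights and the slide fits could not turn the sign either. *Gpi1* reversed with array weights (-0.077), and *Ppara* (-0.16) with array weights (0.0066) and without CIH 3 (0.19, in a range of -0.45 to 0.19 without 1 array). The cause was not tested. Host gene lists, circular RNA classes, shared host genes and normexp on the mean signal were not run. The authors' table lists no mRNA probes. Signal limits control 2 most, with 73.9% of probes well above background.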

Other observations

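The test of a shared rise of PPARA targets was chosen after the values had been seen, as were the probes named here.

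The largest circular RNA difference was at ASCRP4009879, with log2 levels of 2.25, 8.33 and 7.65 on CIH 1, 2 and 3 and 1.60, 0.44 and -0.31 on control 1, 2 and 3. Its difference was 5.50 (SE 1.34, limma, adjusted p = 0.315). ASCRP4007063 had a like profile, at 0.75, 6.85 and 5.31 on the CIH arrays and 0.49, 0.70 and 0.01 on the control arrays, a difference of 3.91 (SE 1.24, adjusted p = 0.315). ASCRP4009879 was the 1 probe that passed without CIH 1 (adjusted p = 0.0436), where the smallest adjusted p of a circular RNA ranged from 0.0436 to 1.0 over the alternatives other than slide 1 alone. These were the 2 that passed with slide 1 alone, but that fit gave every probe an SD of 0.66, against 3.33 and 3.17 between their own CIH arrays, so it is no evidence for them. Each probe has 1 spot per array, so a single bright spot is not ruled out on any 1 array.

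The median differences of dim and bright circular RNA probes had opposite signs under the scaling used. The median difference was 0.16 in the fifth of tested probes with the lowest signal and -0.40 in the fifth with the highest. The looser list held 320 higher and 16 lower probes in the first of these and 188 higher and 171 lower in the second.

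*Acaa2*, *Cpt1a* and *Pex11a* are known targets of the nuclear receptor PPARA, and the hypothesis was tested that the CIH arrays may share a rise of all 3. *Pex11a*, a factor of peroxisome division, had a difference of -0.57 (SE 0.51), against 2.32 for *Acaa2* and 1.9 for *Cpt1a*, so the 3 did not all rise. These values were known when the test was chosen, and *Acaa2* and *Cpt1a* were picked for a small p, so it decides nothing about PPARA. Leaving out 1 array moved *Pex11a* to between -0.98 (without CIH 1) and -0.14 (without CIH 3), below 0 in each case. *Ppara* itself differed by -0.16 (SE 0.44).

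Among the negative probes, 2 of 15 were well above background on all 6 arrays.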
